A study of Homo sapiens with 24 samples.

How the data were processed

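The data are gene-level counts from 24 RNA libraries of cultured human ASC and VFB, 6 per group. Per the labels' protocols, both cell types were expanded in advanced MEM with 5% platelet lysate, 2 U/ml heparin and GlutaMAX, passaged 2 to 3 times and grown to confluence over 9 to 14 days, and libraries were made from 200 ng of RNA with the Illumina TruSeq mRNA protocol. Per the submitters' processing notes, cutadapt, BWA and GATK were used with the human build hg38; the strandedness, the counter, the annotation release and the tool versions are not given in the sources used here. The authors deposited raw counts per gene for 64253 genes, of which 38013 had a count in at least 1 library. A table the authors deposited for ASC against VFB holds the same counts, FPKM values, log2 fold changes and p-values for 13196 genes; its log2 values are ASC minus VFB, and its FPKM values are the authors' and were not tested. Positions are those of the deposited count table.

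Groups came from the labels, and the replicate number from the sample titles. No pair of libraries of a group agreed within sampling noise, with chi-square per degree of freedom from 23.1 to 270.4. Same-numbered ASC and VFB libraries were taken as pairs from the same donor. The pairing comes from the data and not from the labels: over 22 genes whose expression common variants set, 12 of 12 ASC and 12 of 12 VFB libraries correlated best with their own number (0.799 to 0.966, with a median of -0.094 between other numbers). Over all genes 10 of 12 pairs correlated over 0.1 (-0.156 to 0.560), and 8 of 12 ASC and 8 of 12 VFB libraries correlated best with their own number. There each library was compared only with the other cell type's libraries of its own POP or CTRL group, after group means were removed. Over the 22 genes each was compared with all 12. The pairing was accepted after the fits with and without a block had been seen; the test of ASC against VFB stayed without the block, and the block is an alternative. Counts were scaled with TMM and genes kept by filterByExpr (minimum count 10, minimum total 15) in edgeR 4.0.16 under R 4.3.3. Each comparison used edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. POP and CTRL were compared within each cell type, on the 12 libraries of that type. ASC and VFB were compared over all 24 libraries, and the interaction of POP and cell type in a fit of all 4 groups. Printed levels are CPM on TMM-scaled totals, with the mean and SD over libraries. Gene lists, 40 in all with 996 of 999 members matched to the table, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Ratios of genes with 1 to 3 counts carry exact Clopper-Pearson 95% intervals, which cover counting error only.

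Genes named in the text were chosen by a rule fixed before the data were examined. For POP against CTRL it took up to 10 genes per direction that passed at 0.05, and otherwise filled to 5 per direction with the smallest unadjusted p under 0.01 and 2-fold, at a mean of at least 1 CPM. For ASC against VFB it took the 10 largest log2 changes per direction among genes that passed and whose 12 and 12 values did not overlap. For the interaction it took 3 per direction where none passed, and for each list named up to 4 members of smallest p. For the interaction 5 per direction would have been named had they passed. Genes without a symbol, Y-linked genes and the RNAs of X inactivation were left out. Names follow the count table, and 35443 identifiers have a symbol in the reference names.

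Alternatives fixed beforehand were DESeq2 size factors, no filter, a stricter filter (1 CPM in 6 libraries), DESeq2 1.42.0, robust variance shrinkage, limma-voom, all 24 libraries in a single fit, leaving out each library or number, POP as a covariate, CTRL or POP alone, and the replicate number as a block. Group labels were also regrouped up to 100 times. Added after seeing the data was the comparison of ASC with VFB without VFB CTRL replicate 1.

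The scripts were tested on simulated counts with the real means, library sizes and dispersions and independent genes. Each comparison had a single simulated draw with known 2-fold and 4-fold changes. The changed genes tested were 99 of each fold in ASC, and 100 at 2-fold and 94 at 4-fold in VFB. Recovery at an adjusted p depends on how many genes change, so the rates given here need not hold for fewer changed genes. In the ASC comparison (15635 genes) edgeR recovered 54.5% of 2-fold and 80.8% of 4-fold changes, and in VFB (16138 genes) 37% and 89.4%. For ASC against VFB (15870 genes) it recovered 74.2% and 97.9%, and for the interaction (17126 genes) 26.5% and 68.4%. False calls made up 4.29%, 2.42%, 5.71% and 1.06% of edgeR's calls in that order, and 19.4% and 22.9% of DESeq2's calls in ASC and in VFB. Figures were drawn with matplotlib 3.10.9.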

Results

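RNA was sequenced from cultured primary human cells of 2 kinds. Adipose-derived stromal cells (ASC) were grown from abdominal fat removed by liposuction, and vaginal fibroblasts (VFB) were grown from tissue beneath the vaginal epithelium. Each kind came from people with pelvic organ prolapse (POP), a descent of the pelvic organs, and from controls without it (CTRL). The 24 libraries formed 4 groups of 6: ASC CTRL, ASC POP, VFB CTRL and VFB POP. Total counts in genes ranged from 16.1 to 30.1 M (mega) per library, with means of 24.2 M ± 3.28 in ASC CTRL, 23.4 M ± 3.73 in ASC POP, 22.2 M ± 3.50 in VFB CTRL and 23.4 M ± 3.26 in VFB POP (SD, n = 6 each). The gene with most counts was FN1, the extracellular matrix protein fibronectin, in every ASC library, where it took 5.67% ± 0.884 of the counts (SD, n = 12). In VFB the leading gene was COL1A1, COL1A2, COL3A1 or FN1 and took 3.16% ± 1.19 (SD, n = 12). Genes of the mitochondrial genome held 3.33% ± 0.421 of counts in ASC and 4.26% ± 0.769 in VFB (SD, n = 12 each). The labels do not name donors, but the data pair same-numbered libraries of both cell types, so the 24 libraries were not taken as 24 donors. The p-values given here measure the spread between libraries and, except where a block is named, do not use the pairs.

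Cell type was the main axis of variation. Over 17380 genes, the first principal component held 43.9% of the variance and placed the ASC libraries between -83.6 and -45.2 and the VFB libraries between 25.4 and 94.8. The second component held 14.2% and ran from -75.6 to 44.6 within ASC and from -32.3 to 84.5 within VFB. POP and CTRL libraries overlapped on both components.

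**Figure D1:**
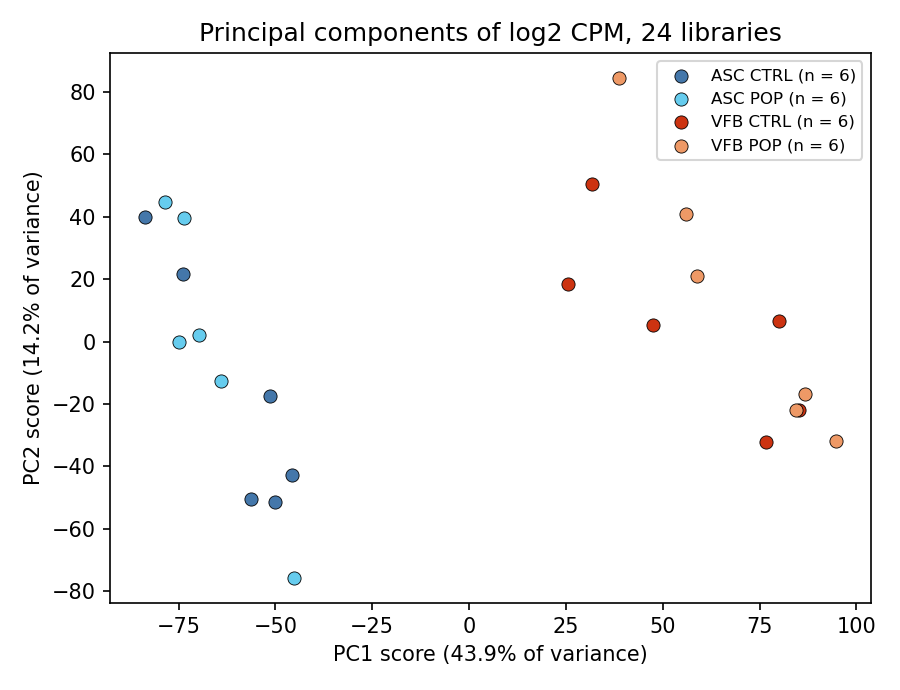
Scores of the 24 libraries on principal components 1 (x axis) and 2 (y axis) of log2 CPM, 1 point per library, coloured by group (n = 6 each). ASC libraries lie between -83.6 and -45.2 on component 1 and VFB libraries between 25.4 and 94.8, while POP and CTRL points are interspersed.

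The first comparison asked which genes differ between POP and CTRL in adipose-derived cells. SULF1, which encodes an extracellular sulfatase that edits heparan sulfate, had the smallest p: its level was 45.0 ± 31.7 CPM (counts per M of library total) in ASC CTRL and 9.85 ± 3.19 in ASC POP (SD, n = 6 each), a log2 fold change of -2.20 with a standard error of 0.43. SERPINB7, a serine protease inhibitor, stood at 65.2 ± 44.1 CPM in CTRL and 27.2 ± 5.64 in POP. Lower mean levels in POP were also measured for TRAPPC3L (2.83 against 0.849 CPM), LRRN3 (1.71 against 0.444 CPM) and KCTD21-AS1 (1.60 against 0.781 CPM), the last an antisense transcript whose reads may not be separable from those of the opposite strand. DOK3, an adaptor of tyrosine kinase signalling, stood at 0.872 ± 0.467 CPM in CTRL and 1.79 ± 0.289 in POP. None of these genes passed the test over all genes. SULF1 lies on chromosome 8 from 69466624 to 69660915 and SERPINB7 on chromosome 18 from 63752935 to 63805376 (hg38).

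By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 15845 genes differed between POP and CTRL in ASC at an adjusted p of 0.05, and the smallest adjusted p was 0.725. At an unadjusted p under 0.05 there were 1040 genes, where 792 would be expected with no difference in any gene. That count ran from 607 without ASC CTRL replicate 6 to 2000 without ASC CTRL replicate 3. Over 100 relabellings of POP and CTRL the median was 447.5. DESeq2 called 1 gene, SULF1 (log2 fold change -2.20, adjusted p 0.00177), and limma-voom called 0, with 1177 and 1053 genes at an unadjusted p under 0.05. At an unadjusted p under 0.01 and a 2-fold change, 24 genes were found, 4 higher and 20 lower in POP. That number was 52 with DESeq2, 37 when all 24 libraries entered the fit, 140 with no filter on low counts and 15 with a stricter filter. It was 45, 57 and 15 without ASC CTRL replicates 1, 3 and 4, and 61, 37, 14 and 12 without ASC POP replicates 7, 10, 11 and 12.

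Gene lists fixed beforehand gave small shifts in ASC. Of the 27 measured inflammatory cytokines and NF-kB targets, 23 had a higher fitted level in POP, with a median log2 change of 0.54 (camera with a preset correlation, adjusted p 1.29e-05; adjusted p = 0.266 with an estimated correlation). Examples are ICAM1, a leukocyte adhesion molecule, at 7.23 ± 4.31 CPM in CTRL and 14.9 ± 4.96 in POP, and IL32, at 15.8 ± 8.09 and 31.2 ± 12.9 CPM. MHC genes had a median log2 change of 0.41 over 16 members (adjusted p 0.00350; adjusted p = 0.874 with an estimated correlation), and TAP1, a peptide transporter of antigen presentation, passed when adjusted over the list alone, at 43.40 ± 4.54 and 64.03 ± 14.4 CPM (adjusted p 0.0261). Of 24 cholesterol synthesis genes 4 had a higher fitted level, with a median of -0.19 (adjusted p 0.00190; adjusted p = 0.910 with an estimated correlation). WNT signalling had a median of -0.34 over 21 genes (adjusted p 0.0368; adjusted p = 0.266 with an estimated correlation); WNT9A passed adjusted over the list alone, at 6.10 ± 1.31 CPM in CTRL and 3.10 ± 0.888 in POP (adjusted p 0.0143). PGRMC2, a membrane progesterone receptor component, passed in the same way among 13 steroid hormone receptors and cofactors, at 81.1 ± 12.7 and 55.5 ± 10.8 CPM (adjusted p 0.0225). That list had a median of -0.19 (adjusted p 0.0368; adjusted p = 0.827 with an estimated correlation). All 40 cell cycle genes had a higher fitted level in POP, with a median of 0.40 (adjusted p 0.0368; adjusted p = 0.910 with an estimated correlation). So did 51 of 70 ribosomal protein genes, with a median of 0.06 (adjusted p 0.0134; adjusted p = 0.910 with an estimated correlation). Proteoglycans and matricellular proteins had a median of -0.33 over 23 genes (adjusted p 0.0456; adjusted p = 0.910 with an estimated correlation), with LUM, lumican, at 1211 ± 621 and 641 ± 219 CPM. In all, 8 of 40 lists passed with the preset correlation, 0 with an estimated one and 0 by fry, and 0 members passed over all genes, against 3 adjusted over the list alone. That adjustment does not correct for the number of lists. Over 40 lists a few such members can be expected with no difference in any gene, so these 3 are not evidence of a POP effect. The median, the mean and the test differed in sign for fibrillar collagens, smooth muscle, adipogenesis, mesenchymal surface, growth factor, endothelial, mesothelial and Schwann lists, none of which passed.

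In vaginal fibroblasts the same question was asked, with a second threshold that the study's design names, an unadjusted p under 0.01 with a 2-fold change. PLAT, the tissue plasminogen activator, stood at 282 ± 116 CPM in VFB CTRL and 742 ± 345 in VFB POP (SD, n = 6 each; log2 fold change 1.39, standard error 0.32). RASSF2, a RAS association domain protein, stood at 21.4 ± 10.7 and 58.8 ± 14.7 CPM. AKAP6, a kinase anchoring protein, stood at 1.46 ± 1.21 and 7.52 ± 3.21 CPM, SDK1, a cell adhesion molecule, at 11.0 ± 3.53 and 28.9 ± 18.6 CPM, and FAM86B3P, a pseudogene whose reads could belong to its relatives, at 1.70 ± 0.617 and 3.42 ± 0.985 CPM. Lower mean levels in POP were measured for MEOX2, a homeobox transcription factor (8.86 ± 6.83 against 1.26 ± 0.984 CPM), CRISPLD1 (7.27 ± 7.61 against 1.40 ± 0.807 CPM), SCG2, a secretory granule protein (3.20 ± 2.55 against 0.610 ± 0.322 CPM), and MT1F, a metallothionein with close paralogs (2.13 ± 1.10 against 0.697 ± 0.321 CPM). The level of HAPLN1 in VFB, a gene for a hyaluronan link protein, was 25.6 ± 54.8 CPM in CTRL and 0.361 ± 0.374 in POP; 1 library, VFB CTRL replicate 1, held 137 CPM, and without it the log2 fold change went from -6.18 to -3.20. None of these genes passed the test over all genes.

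By edgeR, 0 of 16443 genes differed between POP and CTRL in VFB, with a smallest adjusted p of 0.9998, and DESeq2 and limma-voom called 0 as well. At an unadjusted p under 0.05 there were 434 genes, where 822 would be expected with no difference in any gene. DESeq2 gave 508 and limma-voom 411. Leaving out 1 library gave from 310 (VFB CTRL replicate 1) to 725 (VFB CTRL replicate 2). Over 100 relabellings the median was 527. The second threshold gave 48 genes, 12 higher and 36 lower in POP. It gave 92 with DESeq2, 95 when all 24 libraries entered the fit, 164 with no filter on low counts, 25 with a stricter filter, 28 without VFB CTRL replicate 1 and 108 without VFB CTRL replicate 2. The library codes in the labels part POP from CTRL, and if they mark an order of preparation, that order and the disease cannot be told apart.

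No HOXC gene was measured well enough to test in VFB alone. Among the other lists, 7 of 39 passed with the preset correlation, 0 with an estimated one and 0 by fry, and 0 members passed over all genes, against 9 adjusted over the list alone. As in ASC, that adjustment does not correct for the number of lists, so some such members can be expected by chance. All 70 measured ribosomal protein genes had a lower fitted level in POP, with a median log2 change of -0.17 (adjusted p 8.48e-13; adjusted p = 0.649 with an estimated correlation). All 40 cell cycle genes had a higher fitted level in VFB POP, as they had in ASC POP. Their median was 0.38, and the list did not pass in VFB (camera adjusted p 0.323). The unfolded protein response had a median of -0.21, with 3 of 26 genes at a higher fitted level (adjusted p 0.000185; adjusted p = 0.649 with an estimated correlation); HERPUD1 stood at 118 ± 42.7 CPM in CTRL and 80.9 ± 16.4 in POP. Of 12 Schwann and neural markers, 5 passed adjusted over the list alone, all lower in POP (list adjusted p 0.00920; adjusted p = 0.475 with an estimated correlation). They include MAP2, SYT1 and ERBB3, a neuregulin receptor, the last at 0.977 ± 0.458 and 0.464 ± 0.0849 CPM. The 12 pericyte markers had a median of -0.64 (adjusted p 0.00239; adjusted p = 0.506 with an estimated correlation), and NDUFA4L2 passed adjusted over that list alone, at 9.22 ± 11.6 and 2.13 ± 0.869 CPM (adjusted p 0.0358). VFB CTRL replicate 1 held 32.9 CPM of NDUFA4L2 and 11.3 CPM of MAP2, whose group means were 3.12 ± 4.13 and 0.454 ± 0.309 CPM. Without that library the log2 fold change of NDUFA4L2 in VFB went from -2.12 to -1.08 and that of MAP2 in VFB from -2.79 to -1.71. Matrix proteases and their inhibitors had a median of 0.20 over 30 genes (adjusted p 0.0159; adjusted p = 0.475 with an estimated correlation), and PLAT passed adjusted over the list alone (adjusted p 0.0207). HAPLN1 and MT1F did so in lists that were not called (adjusted p 0.0346 and 0.0382). Posterior HOX genes had a median of 0.34 over 8 genes and histones 0.28 over 9 (adjusted p 0.00239 each; adjusted p = 0.614 and 0.475 with an estimated correlation). The median, the mean and the test differed in sign for basement membrane, proteoglycan, skeletal muscle, HOXB, regional transcription factor, mesenchymal surface, complement, senescence, oxidative stress, immune cell and mesothelial lists, none of which passed.

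**Figure D2:**
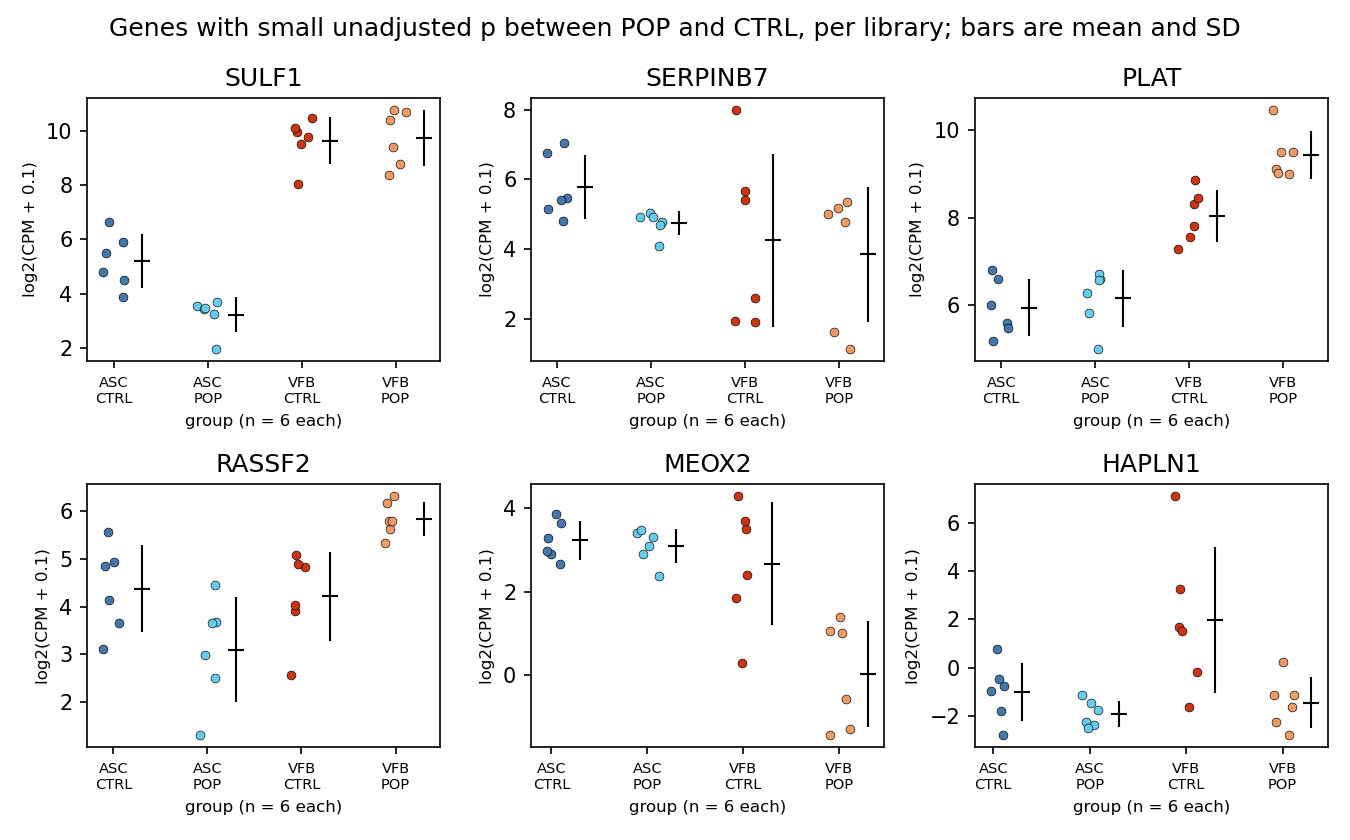
Levels of 6 genes in each library, as log2(CPM + 0.1) on the y axis, by group on the x axis (n = 6 each); points are libraries and bars are the mean and SD of the log2 values. PLAT and RASSF2 are plotted higher in VFB POP, MEOX2 lower, and HAPLN1 shows a single VFB CTRL library at 137 CPM; none passed the test over all genes.

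Whether the POP difference itself differs between cell types was tested with an interaction term. RASSF2 averaged 24.2 ± 14.3 CPM in ASC CTRL and 10.5 ± 6.88 in ASC POP, against 21.4 ± 10.7 and 58.8 ± 14.7 in VFB (SD, n = 6 each). NMT2, an N-myristoyltransferase, averaged 29.2 ± 1.64 and 21.3 ± 3.09 CPM in ASC and 34.2 ± 5.93 and 39.7 ± 3.50 in VFB. SULF1 averaged 897 ± 393 CPM in VFB CTRL and 1033 ± 626 in VFB POP, next to its lower level in ASC POP. MT1F averaged 0.498 ± 0.292 and 1.15 ± 0.449 CPM in ASC, and 2.13 ± 1.10 and 0.697 ± 0.321 in VFB. DCLK3, a kinase, averaged 1.79 ± 1.18 and 3.49 ± 1.51 CPM in ASC and 0.399 ± 0.295 and 0.0343 ± 0.0840 in VFB, and MEOX2 9.65 ± 3.17 and 8.69 ± 2.22 in ASC beside its lower mean in VFB POP. None passed: by edgeR 0 of 17380 genes had an adjusted p under 0.05 (smallest 0.9999). At an unadjusted p under 0.05 there were 421, where 869 would be expected with no interaction in any gene. With the replicate number as a block there were 698. DESeq2 and limma-voom called 0, with 495 and 365 at an unadjusted p under 0.05. Across 15373 genes, which are not independent replicates, the log2 fold changes of POP against CTRL in both cell types had a Pearson correlation of 0.230 and a Spearman correlation of 0.233, and 58.6% had the same sign. Over 100 relabellings of POP and CTRL across the numbers the mean Pearson correlation was 0.246, and the real one was 0.133 without number 6 and 0.144 without number 11.

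The last comparison combined POP and CTRL and asked which genes distinguish ASC from VFB. HOX genes, which encode positional identity along the body axis, were among the genes that differed most. All 6 measured HOXC genes and all 8 measured HOXB genes were lower in VFB, and HOXC8 stood at 40.3 ± 8.22 CPM in ASC and 0.0641 ± 0.121 in VFB (SD, n = 12 each; log2 fold change -9.18, standard error 0.41, edgeR adjusted p 5.55e-14). HOXA13, the most posterior gene of its cluster, stood at 0.0951 ± 0.154 CPM in ASC and 37.3 ± 20.5 in VFB (log2 fold change 8.59). In VFB the higher genes also included DIO2, the deiodinase that activates thyroid hormone (0.0839 ± 0.0896 against 109 ± 98.6 CPM), ALDH1A1, a retinaldehyde dehydrogenase (0.362 ± 0.583 against 201 ± 152 CPM), and CDH6, a cadherin (0.0458 ± 0.0481 against 32.8 ± 33.5 CPM). In ASC the higher genes included SFRP2, a secreted WNT antagonist (87.4 ± 132 against 0.534 ± 0.564 CPM), and NRN1, a small membrane-anchored neuronal growth protein (26.5 ± 19.5 against 0.0504 ± 0.0740 CPM). Across the ASC libraries SFRP2 ran from 1.86 to 440.5 CPM.

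By edgeR 6110 of 16038 genes differed at an adjusted p under 0.05, 3128 higher and 2982 lower in VFB, and 1968 of them by 2-fold or more, 1315 higher and 653 lower in VFB. The 12 ASC and 12 VFB values did not overlap for 505 of the 16038 genes tested, and all 505 were among the 6110. Chance would give a share of 7.4e-05% for an unselected gene if all libraries were exchangeable. The libraries were taken as pairs, and the 6110 were called on the same values. The 505 can therefore not be weighed against that share. DESeq2 called 6480 genes and limma-voom 5962. Within CTRL alone 2067 genes were called and within POP alone 3378; 1529 were called in both, all with the same sign, where independent lists would share 153 higher and 64.5 lower genes. The authors' deposited table lists 13196 genes, of which 5494 had an adjusted p under 0.05; 5142 genes were called in that table and here, all with the same sign, and the log2 fold changes of both had a correlation of 0.999 across genes. A further 896 genes called here are not in the authors' deposited table, among them PCDH10, CCL13 and HOXB9.

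Both HOXB and HOXC lists kept their call when the correlation between genes was estimated (camera, adjusted p 0.0414 and 0.0118). HOXC6, HOXC9 and HOXC10 averaged 45.2 ± 8.29, 11.7 ± 2.30 and 21.1 ± 6.57 CPM in ASC and 0.234, 0.0292 and 0.0461 CPM in VFB; HOXC6 spans its neighbours from 53990624 to 54030823 on chromosome 12, so its reads and those of HOXC8 and HOXC9 may not be fully separable. In HOXA, 3 of 11 measured genes were higher in VFB and 7 lower (adjusted p 0.183); HOXA11 averaged 10.1 ± 2.92 CPM in ASC and 34.4 ± 7.42 in VFB, and HOXA5 8.79 ± 5.80 and 1.57 ± 1.28. In HOXD, 4 of 6 tested genes were lower and 1 higher in VFB (list adjusted p 0.0179; adjusted p = 0.297 with an estimated correlation): HOXD1 averaged 6.74 ± 6.26 CPM in ASC and 0.0328 ± 0.0602 in VFB, and HOXD10 0.139 ± 0.134 and 12.8 ± 9.76. The list of posterior HOX groups had 4 of 9 tested genes higher and 4 lower, a median log2 change of 0.17, a mean of -0.92 and a camera direction of lower (adjusted p 0.579). The filter on low counts left out HOXD11 and HOXD13, which were low in VFB CTRL replicate 1 (0.130 and 0.259 CPM), and it left members of other lists untested too. With no filter HOXD11, at 0.0906 ± 0.102 CPM in ASC and 5.47 ± 3.61 in VFB, and HOXD13, at 0.00374 ± 0.0130 and 5.58 ± 6.42, were higher in VFB (adjusted p 5.93e-09 and 9.05e-10). HOXD then had 4 genes higher and 4 lower, and the posterior groups 7 higher and 5 lower.

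**Figure D3:**
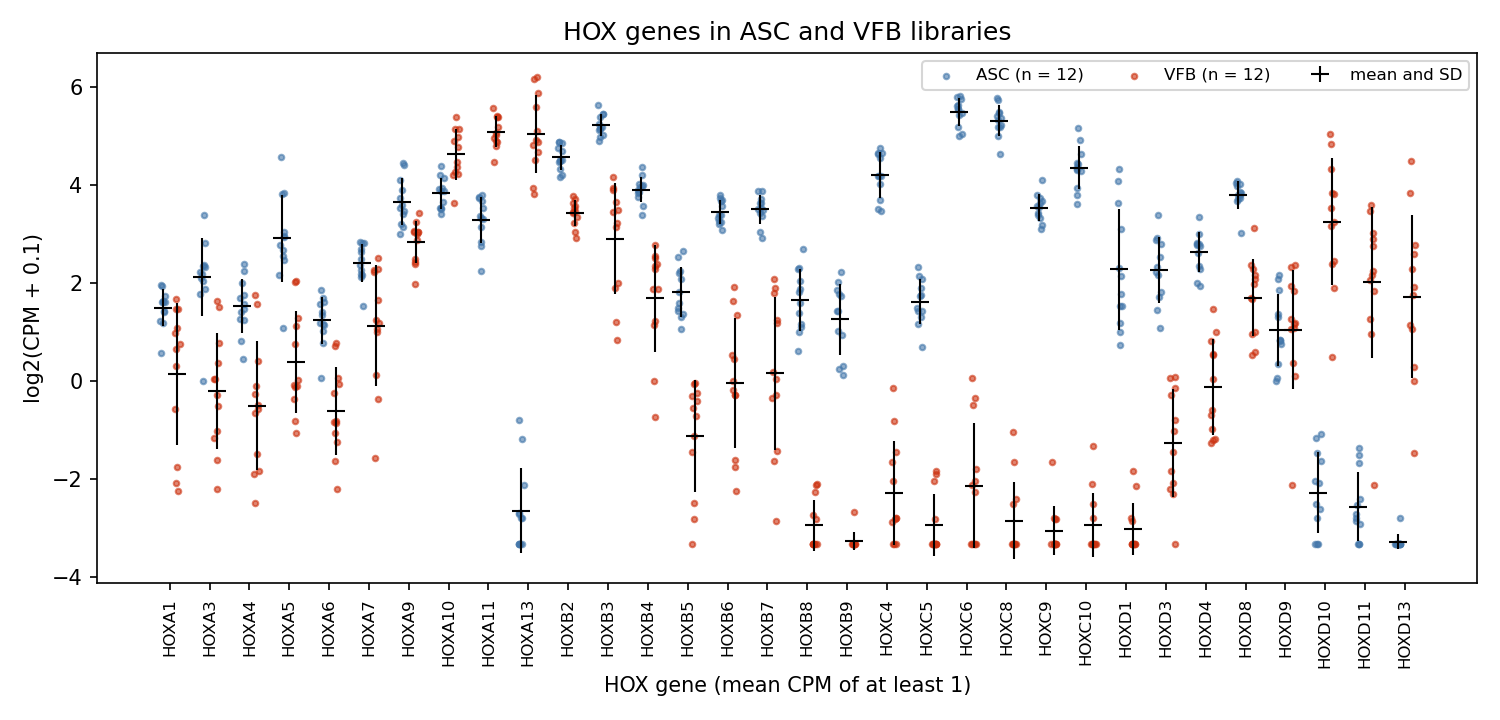
HOX genes with a mean of at least 1 CPM (x axis) as log2(CPM + 0.1) (y axis); points are libraries of ASC (n = 12) and VFB (n = 12), black bars are the mean and SD of the log2 values. HOXC genes lie high in ASC and near the floor of the axis in VFB, while HOXA13 and HOXD10 lie the other way.

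Several genes had 1 to 3 counts in all 12 libraries of the lower cell type, and their ratios are given with exact 95% counting intervals. HPSE2, a heparanase family member, had 1 count in ASC and 6265 in VFB, a depth-scaled ratio of 6550 (1170 to 259000). HOTTIP, a noncoding RNA that overlaps HOXA13 and may share its reads, had 3 and 3640 counts (ratio 1270, 433 to 6150). COL4A6, a basement membrane collagen chain, had 3 and 1327 counts (ratio 462, 158 to 2240), and CCL13, a chemokine, 1 and 1186 (ratio 1240, 222 to 49000). In the other direction SIM1, a transcription factor, had 1103 counts in ASC and 2 in VFB (ratio 528, 146 to 4360), and HOXB9 711 and 1 (ratio 681, 122 to 26900). PCDH10, a protocadherin, and KIAA1211, now named CRACD, averaged 19.8 ± 39.7 and 9.82 ± 4.55 CPM in VFB against 0.0140 ± 0.0285 and 0.0261 ± 0.0355 in ASC. Across the VFB libraries PCDH10 ran from 0.857 to 143.8 CPM. ADD2, a cytoskeletal protein, averaged 6.44 ± 3.57 CPM in ASC and 0.0305 ± 0.0462 in VFB.

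Basement membrane genes were higher in VFB: 14 of 21 rose, 1 fell and 6 did not pass (camera adjusted p 3.71e-08; adjusted p = 0.0456 with an estimated correlation). COL4A5 averaged 3.78 ± 2.69 CPM in ASC and 98.1 ± 31.2 in VFB, LAMA5, a laminin chain, 5.08 ± 2.35 and 43.3 ± 19.4, and NID1, nidogen, 234 ± 34.9 and 644 ± 187. Epithelial markers were higher in the same comparison, with 6 of 9 higher and 0 lower (adjusted p 0.0362; adjusted p = 0.297 with an estimated correlation). KRT19, an epithelial keratin, averaged 3.63 ± 3.13 CPM in ASC and 99.05 ± 81.6 in VFB. Of 17 smooth muscle and myofibroblast genes 8 were higher and 1 lower in VFB (adjusted p 0.0179; adjusted p = 0.515 with an estimated correlation). MYOCD, a coactivator of smooth muscle genes, averaged 1.33 ± 1.26 CPM in ASC and 20.1 ± 11.2 in VFB, and ACTG2, an enteric smooth muscle actin, was 24.2-fold higher in VFB. Of 10 fibrillar collagens 3 were lower and 7 did not pass (adjusted p 0.379). Elastic fibre genes went both ways, with 6 of 22 higher and 5 lower (adjusted p 0.821): FBLN1, fibulin 1, averaged 174 ± 93.7 CPM in ASC and 1475 ± 837 in VFB, and MFAP5, a microfibril protein, 420 ± 234 and 146 ± 120. Among proteoglycans and matricellular proteins 7 were higher and 8 lower (adjusted p 0.949); TNXB, tenascin X, averaged 1.33 ± 1.05 CPM in ASC and 82.2 ± 83.4 in VFB.

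Transcription factors of regional identity differed in both directions, with 21 of 43 higher and 15 lower in VFB (adjusted p 0.325). GATA2 averaged 0.588 ± 0.326 CPM in ASC and 30.8 ± 9.88 in VFB, ISL1 0.0574 ± 0.0747 and 5.39 ± 1.82, and NR2F1 4.34 ± 1.73 and 99.3 ± 42.4. TBX15, a T-box factor, averaged 34.2 ± 14.5 CPM in ASC and 0.357 ± 0.350 in VFB. The oestrogen receptor gene ESR1 averaged 0.129 ± 0.111 CPM in ASC and 12.8 ± 9.27 in VFB, and HSD11B1, which regenerates cortisol, 0.125 ± 0.0780 and 6.29 ± 3.97. As a list, steroid hormone receptors and cofactors had 4 of 15 higher and 5 lower (adjusted p 0.494). The filter on low counts left out the progesterone receptor gene PGR, at 0.00722 ± 0.0175 CPM in ASC and 2.70 ± 2.25 in VFB. With no filter that list had 6 genes higher, PGR among them, and 5 lower. In WNT signalling 8 of 21 genes were higher and 10 lower (adjusted p 0.325): SFRP1 averaged 7.52 ± 3.68 CPM in ASC and 385 ± 337 in VFB, opposite to SFRP2. In TGF-beta and BMP signalling 11 of 26 were higher and 9 lower (adjusted p 0.569); BMP4 averaged 2.88 ± 1.83 CPM in ASC and 49.98 ± 20.96 in VFB, and GDF5 24.3 ± 6.88 and 5.61 ± 2.94. Of 18 adipogenesis and adipocyte genes 7 were higher and 6 lower, with a median of 0.30 and a camera direction of lower (adjusted p 0.977); DGAT2, which makes triglycerides, averaged 8.69 ± 2.47 CPM in ASC and 0.892 ± 0.645 in VFB, and PDK4 0.166 ± 0.286 and 12.7 ± 13.6.

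Complement genes were higher in VFB by count, 12 of 16 with 0 lower (adjusted p 0.000976; adjusted p = 0.452 with an estimated correlation). With no filter on low counts 14 were higher and 0 lower. C7, among those 14, averaged 0.0485 ± 0.0747 CPM in ASC and 27.7 ± 36.7 in VFB. The unfolded protein response went the other way, with 19 of 26 genes lower in VFB and 0 higher (adjusted p 1.13e-05; adjusted p = 0.297 with an estimated correlation). EDEM1, which directs misfolded proteins to degradation, averaged 91.5 ± 14.4 CPM in ASC and 59.7 ± 9.20 in VFB. Of 24 cholesterol synthesis genes 12 were lower and 1 higher (adjusted p 0.000821; adjusted p = 0.515 with an estimated correlation), with INSIG1, a sterol sensor, at 180 ± 117 and 51.7 ± 28.9 CPM. In growth factor signalling 14 of 32 genes were higher and 6 lower (adjusted p 0.0254; adjusted p = 0.0732 with an estimated correlation), with HGF, hepatocyte growth factor, at 6.28 ± 5.14 CPM in ASC and 219 ± 152 in VFB. Mesothelial markers had 5 of 9 higher and 1 lower (adjusted p 0.0354; adjusted p = 0.297 with an estimated correlation). WT1, listed among them, averaged 0.0374 ± 0.0604 CPM in ASC and 9.90 ± 5.06 in VFB.

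Inflammatory genes had 11 of 27 higher and 4 lower in VFB (adjusted p 0.0345; adjusted p = 0.452 with an estimated correlation): CXCL12, a chemokine, averaged 103 ± 53.7 CPM in ASC and 556 ± 316 in VFB. CXCL5 averaged 6.11 ± 4.22 CPM in ASC and 0.305 ± 0.227 in VFB. MHC genes had 9 of 16 higher and 1 lower (adjusted p 0.0254; adjusted p = 0.452 with an estimated correlation), histones 5 of 9 higher (adjusted p 0.00845; adjusted p = 0.299 with an estimated correlation) and mitochondrially encoded genes 4 of 13 higher (adjusted p 0.0254; adjusted p = 0.515 with an estimated correlation). Mesenchymal surface markers had 9 of 21 higher and 2 lower (adjusted p 0.0530, and 0.0459 with the replicate number as a block; adjusted p = 0.181 with an estimated correlation and no block), with CD9, a tetraspanin, at 17.1 ± 11.8 and 133 ± 53.5 CPM. Osteogenic and chondrogenic genes had 3 of 12 higher and 5 lower (adjusted p 0.494), with RUNX2, a bone transcription factor, at 73.8 ± 37.6 and 13.5 ± 2.23 CPM; their median was -0.76 and their mean 0.11. Matrix proteases and inhibitors had 10 of 32 higher and 10 lower (adjusted p 0.569), a median of -0.15 and a mean of 0.03. Senescence genes had 5 of 22 higher and 3 lower (adjusted p 0.494), endothelial markers 3 of 7 and 1 (adjusted p 0.267), Schwann and neural markers 5 of 8 and 1 (adjusted p 0.209), pericyte markers 2 of 10 and 1 (adjusted p 0.821) and skeletal muscle genes 2 of 4 and 1 (adjusted p 0.919). Immune cell markers had 0 of 4 higher and 1 lower, a median of 0.04 and a mean of -0.39 (adjusted p 0.457), and 0 of 70 ribosomal protein genes passed (adjusted p 0.214). In all, 18 of 40 lists passed with the preset correlation, 3 with an estimated one and 27 by fry. Adjusted over the list alone, 1 cell cycle gene was lower in place of 10, 17 cholesterol genes in place of 12, 8 HOXA genes in place of 7, 2 fibrillar collagens in place of 3, 6 elastic fibre genes in place of 5 and 11 proteases in place of 10. Counts adjusted over the list alone also differed for adipogenesis (8 higher, 7 lower), osteogenic genes (4 and 6), inflammatory genes (12 higher), regional transcription factors (22 higher), growth factors (15 higher), immediate early genes (3 higher), mesothelial markers (6 higher) and mitochondrially encoded genes (6 higher); in the remaining lists they were the same. With no filter on low counts more members were tested in many lists, and counts changed in most of them. Examples are skeletal muscle (3 higher, 5 lower), pericyte (4 and 1), Schwann and neural (10 and 1), and epithelial markers (11 and 0). Further examples are the unfolded protein response (0 higher, 13 lower), regional transcription factors (24 and 19), growth factors (17 and 9), proteoglycans (10 and 8), smooth muscle (11 and 1) and WNT signalling (11 and 10). Others are mesothelial (6 and 2), immune cell (0 and 4), adipogenesis (11 and 6), osteogenic (5 and 6), cell cycle (0 and 5) and mitochondrially encoded genes (2 and 0), besides HOXD and the posterior HOX groups.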

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

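The tests of ASC RNA and of depth in VFB CTRL replicate 1 were chosen after its values were seen. Of 84 values per group of 6 libraries that were checked for a library far from the others, 10 had one. A rate of 1 in 20, here 4.2, would hold for normally distributed values. The values were checked without logs, and the genes among them were chosen from these same libraries. The 10 can therefore not be weighed against 4.2. The highest libraries were ASC CTRL replicate 6 for the mitochondrial share (4.08% of counts, others 3.00 to 3.39%), ASC CTRL replicate 4 and ASC POP replicate 11 for LRRN3 (4.51 CPM, others 0.520 to 2.00, and 1.06 CPM, others 0.217 to 0.453), VFB POP replicate 10 for PLAT (1418 CPM, others 509 to 729), VFB CTRL replicate 3 for CRISPLD1 (22.4 CPM, others 1.29 to 6.21), and VFB POP replicate 8 for HAPLN1 (1.08 CPM, others 0.0451 to 0.359) and DCLK3 (0.206 CPM, others 0).

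VFB CTRL replicate 1 held 3 of these values: HAPLN1 at 137 CPM (others 0.225 to 9.52), NDUFA4L2 at 32.9 CPM (others 3.29 to 5.42) and MAP2 at 11.3 CPM (others 0.450 to 2.69). It also lay nearest to ASC on principal component 1, at 25.4, with the other VFB libraries from 31.7 to 94.8. RNA of ASC mixed into the library was tested on 25 genes at least 64-fold higher in ASC. They stood at 2.49% of their ASC level (95% counting interval 2.19 to 2.82%), against 0.692% in the other VFB libraries. The 25 genes were chosen for a low level in those other libraries, without this library. The 0.692% is therefore low by choice, and the gap to 2.49% cannot be read as an excess. On a linear scale between the cell types the shift on component 1 would need 31.9%, which these genes argue against. Component 1 rests on log2 CPM and need not follow the share of mixed RNA linearly. Mixed RNA would bring these genes in at an even share of their ASC levels, but their 251 counts were uneven. NDNF, the highest single gene at 21.4%, held 93 of them, CH25H 52 and HAS1 51. SFRP2, HOXC8 and HOXC10 had 0 counts in VFB CTRL replicate 1, HOXC6 had 3, and HOXC4, HOXC5 and HOXC9 had 1 each. HOXC6 and HOXC8 averaged 45.2 and 40.3 CPM in ASC. The HOXC genes argue against an even share near 2.49%, while a smaller share cannot be excluded. Low depth is argued against by its 24.7 M counts, above the mean of 22.6 M in the other VFB libraries. A share of ASC RNA below 2.49% stays open, and so does a difference of the donor or the culture, which was not tested.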

How the results depend on the processing

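The comparison of ASC with VFB without VFB CTRL replicate 1 was chosen after seeing the data. Every other setting tried left 0 calls between POP and CTRL in VFB and 0 for the interaction; in ASC DESeq2 called 1 gene, and the others 0. The genes at an unadjusted p under 0.01 and 2-fold in ASC went from 24 to 140 with no filter, 15 with the stricter filter, 52 with DESeq2 and 37 with all 24 libraries in one fit, and in VFB from 48 to 164, 25, 92 and 95 in that order. The filters also changed the number of genes tested, in ASC from 15845 to 33966 with no filter and 14109 with the stricter filter. The cause of these changes was not tested for any of the 4 settings. Leaving out each library gave 12 to 61 in ASC and 28 to 108 in VFB. For ASC against VFB, leaving out each number gave 5103 to 6447 calls, and 1854 to 2095 of 2-fold or more; CTRL alone gave 2067 calls (1306 at 2-fold) and POP alone 3378, with fewer libraries, and no filter gave 4172 at 2-fold with more genes tested. Without VFB CTRL replicate 1 there were 6097 calls and 2072 at 2-fold. The correlation of POP effects ran from 0.133 to 0.336 without each number, and was 0.223 at a mean of at least 10 CPM and 0.231 with DESeq2 size factors. DESeq2 size factors moved the median log2 change by 0.00999 between the cell types.

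With the replicate number as a block, 7238 genes differed between ASC and VFB, 5938 of them among the 6110, all with the same sign, 172 were lost and 1300 gained, and 0 interaction genes passed. The block brought 1 list past the threshold with the preset correlation, mesenchymal stromal surface markers (adjusted p = 0.181 with an estimated correlation and no block), and turned the sign of another that was not called, adipogenesis and adipocyte (adjusted p 0.826). Among the genes followed it brought COL5A3 and RPS2 past the threshold and took MYH3 and GAP43 below it, and it changed no other call of a list or a followed gene.

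Of 163 genes followed between ASC and VFB, 47 changed their call or sign in some fit. Over 3746 refits 115 lost the call, 5 gained it and 6 changed sign, the last all for genes that had not passed, for causes that were not tested: LCP1 (-0.0152 with limma-voom, -0.355 in POP alone, -0.0421 without VFB CTRL replicate 1, -0.0328 without replicate 1 and up to 0.612 without replicate 12), CORO1A (0.144) and RPL8 (0.0497), the last 2 in CTRL alone. By fry, fibrillar collagens and epithelial markers changed sign in ASC (adjusted p 0.988 each). A stricter filter, or CTRL alone, left 9 gene tests without a value, and DESeq2 gave no adjusted p for HAPLN1 and NDUFA4L2 in VFB.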

Other observations

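The tests chosen after the result was seen are the splits for the 3 counts of 0, the splits that part all pairs, the splits for an unadjusted p under 0.05, and the filters on low counts and on a level in every library. Between ASC and VFB, single genes of further lists also differed. Redox genes included GCLC, which starts glutathione synthesis, at 8.45 ± 1.49 CPM in ASC and 33.2 ± 10.5 in VFB, TXNRD1, thioredoxin reductase, at 145 ± 39.4 and 458 ± 129, and the selenium carrier SEPP1 at 2.08 ± 2.42 and 185 ± 213 (SD, n = 12 each); 8 of 23 in their list were higher and 2 lower in VFB (edgeR; camera adjusted p 0.0635). Immediate early genes had 8 of 20 lower and 2 higher in VFB (camera adjusted p 0.0736), with IER3 at 100.4 ± 51.9 and 30.1 ± 12.4 CPM and MYC at 56.6 ± 13.9 and 26.0 ± 8.96. Hypoxia and glycolysis genes had 10 of 29 lower and 1 higher (adjusted p 0.0254; adjusted p = 0.609 with an estimated correlation), with the glucose transporter SLC2A1 at 65.1 ± 56.5 and 18.9 ± 15.8 CPM. The interferon-stimulated list held genes that moved apart: IFIT1 stood at 10.9 ± 4.41 CPM in ASC and 54.9 ± 21.9 in VFB, and IFI27 at 59.0 ± 41.6 and 10.8 ± 4.66 (10 of 30 higher, 4 lower; adjusted p 0.0194; adjusted p = 0.515 with an estimated correlation). In cell cycle genes 10 of 40 were lower and 0 higher in VFB, and 5 lower with no filter on low counts (adjusted p 0.00170; adjusted p = 0.700 with an estimated correlation), with the replication licensing factor MCM6 at 113 ± 39.3 and 59.8 ± 22.2 CPM.

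Chance alone is argued against for a count of 6110 between ASC and VFB: 1 of 100 splits, the real one, gave as many, and the highest other gave 1. The splits bear on the count as a whole and not on single genes among the 6110. The other splits mix both cell types on each side, so the difference between cell types adds to their spread and lowers their counts. Those others part 2 to 10 of the 12 pairs of same-numbered libraries, while the real split parts all 12. Of 100 splits that part all 12, 1, the real one, gave as many (highest other 1761), and with the number as a block 1, the real one, gave its 7238 (highest other 1). Chance cannot be excluded for the genes at the second threshold between POP and CTRL. In ASC 47 of 100 splits of the same libraries gave at least the 24 genes at an unadjusted p under 0.01 and 2-fold (highest other 747), and in VFB 40 of 100 gave at least the 48 (highest other 695). Nor can it be excluded for the 1040 and 434 genes at an unadjusted p under 0.05, which 21 of 100 splits reached in ASC (highest other 4703) and 65 of 100 in VFB (highest other 4543). For the counts of 0 at an adjusted p of 0.05 the splits decide nothing, since each of the 100 gives at least 0 in ASC (highest other 1442), in VFB (highest other 373) and for the interaction (highest other 0). Any gene was called in 2 of the 100 splits in ASC and in 4 of the 100 in VFB. Some splits called 1442 and 373 genes, or had 747 and 695 at the second threshold. Whether those follow a structure among the samples other than POP and CTRL was not tested.

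The hypothesis that same-numbered ASC and VFB libraries come from the same donor was tested for the correlation of POP effects, 0.230. Chance cannot be excluded for it: over 100 relabellings of POP and CTRL across the numbers 53 gave a correlation at least as high (highest other 0.561). The mean over relabellings was 0.246 with numbers matched and 0.00347 (standard error 0.0185) with the numbers of 1 cell type shuffled. Over 22 genes whose expression common variants set, listed before the test, 12 of 12 ASC libraries matched the VFB library of their own number best, where about 1 is expected by chance. These values are consistent with shared donors, which may give such a correlation with no effect of POP.

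The authors' deposited table leaves out 896 genes called here between ASC and VFB. The outlier filter of DESeq2 is argued against as the main cause, since 1.07% of the 560 above the lowest mean count listed had no p under it, and so is a filter on mean counts alone, since 37.5% of the 896 lie below that mean of 20.8. A candidate explanation is a filter on a level in every library of 1 cell type: 98.2% of the 896 genes lie under 1 CPM in at least 1 library of each cell type, against 0.242% of listed genes. That level in every library of a cell type is met by 13196 genes, 13164 of them listed. It was found by trying several count and CPM minimums on the same table, so it is a hypothesis only.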
